A study of Drosophila melanogaster with 4 samples.

How the data were processed

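Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 monomethylated at lysine 27 (H3K27me1) in instar 3 larvae of the wild-type Oregon-R strain of Drosophila melanogaster. Per the labels, tissue was homogenized, fixed with formaldehyde and sonicated, and the chromatin was precipitated with a rabbit polyclonal antibody sold by Millipore. The series holds 2 ChIP samples and 2 input samples. Each ChIP sample has 1 list of enriched regions, and 1 further list belongs to the whole series. No input file was analysed here, so no background level can be set beside the ChIP values. The labels call the ChIP samples replicates without saying whether they came from separate larval collections, so the spread between them may be technical.

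Per the submitters' processing notes, Bowtie 0.12.7 was used, with no role stated. Per the file headers, positions are on FlyBase release 5 and each line is a region of significant enrichment. The region caller, its threshold, the use of the input and the way the replicates entered the whole-series list are not given in the sources used here. The deposited value of each region is an enrichment score, which the authors computed, and its scale is not stated per the file headers. Steps between the 20 highest distinct scores of a list were compared with logarithms of ratios of whole numbers up to 20, with a tolerance of 1e-06. Of 190 such steps, 26 in replicate 1, 43 in replicate 2 and 87 in the whole-series list were base-2 logarithms of such a ratio. None matched a natural logarithm in any list, and at most 4 matched a base-10 logarithm. The scores are therefore treated as values on a log2-like scale: differences are given, and no fold is computed from them. Read counts and library depth are unknown, so no statement about sequencing depth can be made and no counting error of reads can be given.

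Regions were used as deposited. Scaffold lengths were taken from the headers of the lists. A single region of replicate 1 and 2 regions of the whole-series list ran past the end of their scaffold and were trimmed to it. The covered share of a scaffold is the number of bases inside regions over its length. Scaffolds were grouped as the 4 large autosomal arms (2L, 2R, 3L and 3R), X, chromosome 4, the 6 scaffolds of heterochromatin placed on a chromosome (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and U, the unplaced sequence. Unsequenced or repetitive bases count in these lengths, which lowers the covered share where reads cannot be placed.

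Regions of the replicates were called shared when they overlapped by at least 1 bp. The overlap was compared with 1000 circular shifts of the regions of replicate 2 within each scaffold, which keep their number, width and spacing. The test is one-sided, and the smallest p it can give is 0.001. Simulated lists of 6551 regions were set against the real regions of replicate 1 on the arms, with 100 shifts each. This procedure called 10 of 10 lists with planted overlap and 0 of 5 lists placed at random. Planted regions were exact copies of replicate 1 regions, and the others were placed without the clustering of real lists. False calls between clustered lists were therefore not tested. Scores were compared across merged regions that hold regions of both replicates. With 2 replicates an exact sign-flip test of a difference between chromosomes cannot give a two-sided p below 0.5, so a further test was chosen after the data were examined: windows of the length of X or of chromosome 4 were moved in 10 kb steps along the joined arms, and the value of the chromosome was ranked among them (two-sided, 12 relations, Benjamini-Hochberg adjusted). Neighbouring windows share most of their bases, and this test compares positions in these samples, not samples. The joined arms include the chromosome under test, so its windows were later also set against windows along the 4 autosomal arms alone, as a description without a p. Shared regions and bases by width were set against 1000 shifts of each width class. Intervals on shares of regions are 95% Wilson intervals, which treat regions as independent and cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

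The regions named in the text were chosen by a rule set before the data were examined: the 10 longest and the 5 highest-scoring regions of the whole-series list, the highest-scoring region of each replicate, and the 10 whole-series regions at least 90% covered in both replicates with the highest value of the lower of their 2 replicate scores. Comparisons of promoters, exons, introns, gene bodies and gene lists were planned and were not made. They need gene positions on release 5, while the gene table used here is on release 6, so no gene is named. Alternatives were another overlap rule, regions at or above the median score of each list alone, regions within 1 kb joined, the arms alone, a width minimum, the whole-series list in place of the replicates, and each replicate alone.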

Results

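H3K27me1 was profiled by ChIP-seq in instar 3 larvae of wild-type Drosophila melanogaster. This mark is the monomethylated form of the histone residue whose trimethylated form is bound by Polycomb. The data comprise 2 ChIP replicates, each with its own list of enriched regions, and 1 list for the whole series. Replicate 1 had 8209 regions over 26.9 Mb and replicate 2 had 6901 regions over 21.8 Mb. The replicates averaged 7555 ± 925 regions and covered 14.4% ± 2.1 of the assembly (SD, n = 2). The whole-series list had 12362 regions over 41.4 Mb, or 24.6% of the assembly. The depth of the libraries is unknown, and the scores of regions are those the authors deposited.

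H3K27me1 regions were mostly a few kilobases wide, with a minority of long blocks. The median width was 2222 bp in replicate 1 and 2158 bp in replicate 2. Regions of 10 kb or more numbered 268 in replicate 1 and 182 in replicate 2, and held 13.9% and 12.8% of the covered bases. The longest regions of the 3 lists overlapped one another on 3L, and spanned 50.1 kb in replicate 1, 57.6 kb in replicate 2 and 78.3 kb in the whole-series list. Wider regions had higher scores, with a Spearman correlation across regions of 0.65 in replicate 1 and 0.57 in replicate 2. Regions are not independent replicates, so no p-value is attached to these correlations.

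The first comparison asks whether both replicates marked the same parts of the genome. They shared 17.5 Mb of 31.2 Mb covered in either, a Jaccard index of 56.1%. Shifted regions gave a mean of 10.6% and at most 14.6% over 1000 shifts (one-sided permutation p = 0.001, the smallest the shifts can give). Of the regions of replicate 1, 66.5% (95% Wilson interval 65.5 to 67.6) overlapped a region of replicate 2. Of the regions of replicate 2, 81.6% (80.6 to 82.5) overlapped a region of replicate 1, against a mean of 34.0% when shifted.

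Long H3K27me1 blocks were found by both replicates almost without exception, and short regions often were not. Among regions of 10 kb or more, 267 of 268 in replicate 1 and 182 of 182 in replicate 2 were shared. Among regions under 2 kb, 40.2% (38.5 to 41.9) in replicate 1 and 63.2% (61.4 to 65.0) in replicate 2 were shared. Wide regions meet others more often by chance: shifted regions of 10 kb or more gave a mean of 49.1% in replicate 1 and 58.0% in replicate 2, against 23.7% and 28.4% under 2 kb. Counted in bases, which shifting puts at 16.8% to 21.7% in every width class, 89.4% and 95.02% were shared at 10 kb or more and 32.8% and 54.7% under 2 kb. Regions of replicate 1 without a partner had a median width of 1664 bp and a median score of 0.52, against 2971 bp and 0.61 for shared regions. In replicate 2 the corresponding values were 1562 bp and 0.52 against 2490 bp and 0.57. Across 4725 merged regions present in both replicates, the scores correlated with a Spearman coefficient of 0.66 and a Pearson coefficient of 0.71, as a description across regions.

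**Figure D1:**
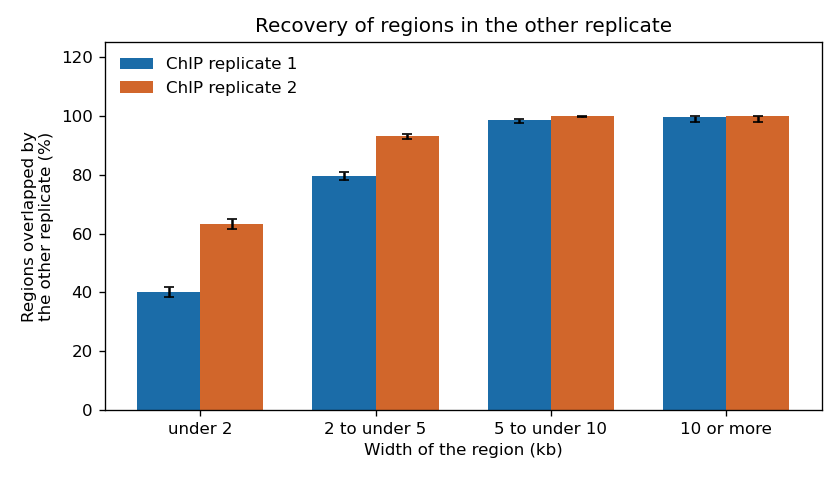
Share of regions overlapped by at least 1 bp by a region of the other replicate (vertical axis, percent) by width of the region (horizontal axis, kb). Bars are the regions of each ChIP replicate and error bars are 95% Wilson intervals. The share rises from 40.2% and 63.2% under 2 kb to 99.6% and 100% at 10 kb or more.

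Overlap between the replicates was higher on the autosomal arms and X than on the placed heterochromatin and U. The Jaccard index was 58.1% on the 4 autosomal arms, 53.8% on X and 45.4% on chromosome 4, which is small and largely heterochromatic. It was 29.5% on the placed heterochromatin scaffolds and 18.4% on U. Of the regions of replicate 1, 68.1% (67.0 to 69.3) were shared on the autosomal arms and 44.9% (38.8 to 51.2) on the placed heterochromatin. In replicate 2 these shares were 84.5% (83.5 to 85.5) and 40.2% (34.4 to 46.2). On chromosome 4 the shares were 70.0% (58.5 to 79.5) in replicate 1 and 56.8% (45.4 to 67.4) in replicate 2. For the Jaccard index, shifted regions gave means of 10.6%, 11.6%, 8.0%, 3.3% and 0.76% in the same order, and each observed value lay above all 1000 shifts (one-sided adjusted permutation p = 0.001, 5 relations). The smaller number of regions in heterochromatin, 245 in replicate 1 and 264 in replicate 2, limits the precision there. Those regions were also narrower, with medians of 1676 and 1699 bp against 2285 and 2238 bp on the autosomal arms. Scores of merged regions present in both replicates did not follow the overlap. Their Spearman coefficient was 0.65 on the autosomal arms, 0.63 on X and 0.46 on chromosome 4 (39 regions). It was 0.67 on the placed heterochromatin (90 regions) and 0.87 on U (27 regions).

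The second comparison places the regions on the chromosome classes. H3K27me1 regions covered 19.4% ± 2.9 of the autosomal arms (SD, n = 2), from 17.5% ± 2.1 on 2L to 21.8% ± 3.8 on 2R. They covered 21.1% ± 3.7 of X and 15.1% ± 3.1 of chromosome 4. Regions at or above the median score alone covered 12.5% of the autosomal arms and 6.88% of chromosome 4. Such a cut keeps fewer regions on chromosome 4, where scores were lower (below), so this drop is not separate evidence on coverage. The placed heterochromatin scaffolds had 5.98% ± 0.44 of their bases covered and U had 1.52% ± 0.04. Within each replicate the placed heterochromatin was covered 0.31 ± 0.07 times as much as the autosomal arms, and in the whole-series list 0.60 times. Bases to which reads cannot be placed are included in the scaffold lengths, and their number is unknown here. Among the heterochromatin scaffolds, XHet was the most covered, with 12.5% ± 2.1, and YHet had no region in replicate 1 and 1 in replicate 2. XHet was covered 0.65 and 0.63 times as much as the autosomal arms in the replicates, over 11 and 8 regions. In the whole-series list it was covered 1.21 times as much, over 34 regions. None of the 3 lists had a region on Uextra.

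X was covered slightly more than the autosomal arms in each replicate. The ratio of X to the autosomal arms was 1.11 in replicate 1 and 1.07 in replicate 2, and a mean of 1.40 among regions at or above the median score. A cut at the median of the whole list keeps more regions on X, where scores were higher (below). The value of 1.40 is therefore not separate evidence on coverage. Among windows of the length of X along the joined arms, which include X, the covered share of X was not extreme in replicate 1 (two-sided adjusted permutation p = 0.35) or in replicate 2 (adjusted p = 0.45). Along the autosomal arms alone, 88.6% and 86.6% of windows of its length were covered no more than X in the replicates, and 99.3% in the whole-series list. Only 4 such windows fit without shared bases, so these windows cannot decide whether the coverage of X is unusual. Chromosome 4 was covered 0.60 times as much as the autosomal arms in replicate 1 and 1.00 times as much in replicate 2, so its mean ratio of 0.80 ± 0.28 rests on replicate 1.

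**Figure D2:**
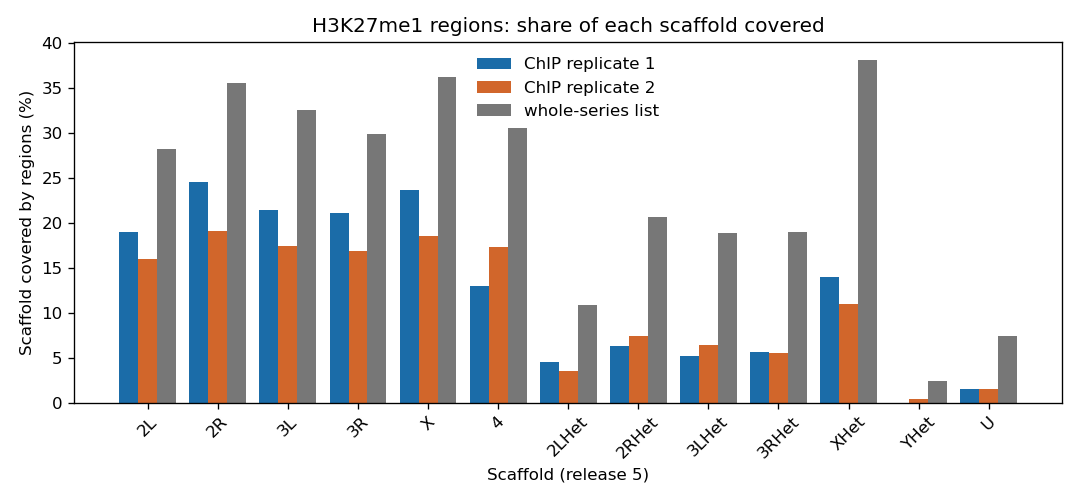
Share of each release 5 scaffold covered by H3K27me1 regions (vertical axis, percent) in ChIP replicate 1, ChIP replicate 2 and the whole-series list (bars). The autosomal arms and X lie between 15.97% and 24.5% in the replicates, the large heterochromatin scaffolds 2RHet, 3LHet and 3RHet between 5.2% and 7.4%, and U at about 1.5%.

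Regions on X had higher scores than regions on the autosomes. The median score on X was 0.64 in replicate 1 and 0.63 in replicate 2, against 0.55 in both on the 4 autosomal arms. The difference was 0.086 ± 0.005 (SD, n = 2), and 0.030 among regions at or above the median score of each list. The 4 autosomal arms lay between 0.54 and 0.56 in the mean of the replicates, so X stood above each of them in both replicates. The test of windows along the joined arms gave a two-sided adjusted permutation p of 0.0068 in each replicate (12 relations), but X itself is part of those arms and the test was chosen after X was seen to be high. Along the autosomal arms alone, the highest median of a window of the length of X was 0.57 in replicate 1 and 0.56 in replicate 2; only 4 such windows fit without shared bases, so no p is given. With 5 large arms, an exact permutation of arms cannot give a p below 0.2.

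The median score on chromosome 4 minus that on the autosomal arms was -0.064 in replicate 1 and -0.047 in replicate 2, and a mean of -0.0037 among regions at or above the median score of each list. That difference did not pass the test of windows along the joined arms (two-sided adjusted permutation p = 0.15 and 0.20). Along the autosomal arms alone, 0.02% and 0.16% of windows of its length had a median as low. That share counts low windows only, whereas the test is two-sided, so they cannot be set against each other. Only 71 windows of that length fit along the autosomal arms without shared bases. The joined arms also hold X, where scores were higher. The central range of their windows reached 0.679 in replicate 1 and 0.655 in replicate 2. Along the autosomal arms alone the highest window had 0.646 and 0.627, so high windows on X weighed in the two-sided test. Chromosome 4 was also low among the joined-arm windows, whose central range began at 0.509 in replicate 1 and 0.507 in replicate 2. Its medians were 0.489 and 0.498. Regions on the placed heterochromatin had median scores above those on the autosomal arms by 0.065 ± 0.015, and regions on U by 0.20 ± 0.04 (SD, n = 2). For the placed heterochromatin this was 0.034 among regions at or above the median score and 0.11 in the whole-series list. The highest scores came from such scaffolds and were seldom shared. Of the 20 highest-scoring regions of replicate 1, 19 lay outside the arms and 2 overlapped a region of replicate 2. Of the 20 highest in replicate 2, 17 lay outside the arms and 3 overlapped a region of replicate 1.

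**Figure D3:**
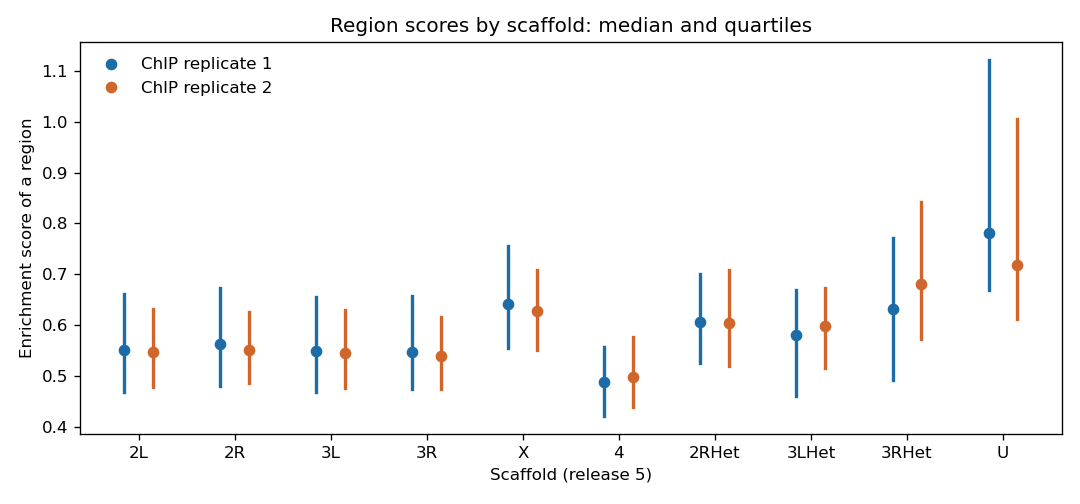
Enrichment score of regions (vertical axis, as deposited, log2-like) by release 5 scaffold in the ChIP replicates. Points are medians and lines run from the lower to the upper quartile. X lies at 0.64 and 0.63, above the 4 autosomal arms at 0.54 to 0.56, and chromosome 4 lies at 0.49 and 0.50.

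Along the large arms, stretches rich and poor in H3K27me1 regions alternated, and the replicates followed one another. Over 117 full bins of 1 Mb on these arms, the covered share ran from 4.70% to 36.1% with a median of 19.5%. The replicates correlated across bins with a Spearman coefficient of 0.93, as a description across bins. The most covered bin was 3R from 5 to 6 Mb, with 36.1% ± 3.9 (SD, n = 2). It was followed by the first Mb of 3R with 34.1% ± 3.1 and by X from 13 to 14 Mb with 33.6% ± 3.8. The least covered was 2L from 15 to 16 Mb, with 4.70% ± 1.08, followed by 3R from 13 to 14 Mb with 6.14% ± 1.33 and 2L from 17 to 18 Mb with 6.42% ± 1.17.

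Long stretches of the arms held no H3K27me1 region in any of the 3 lists. The longest was 376 kb on 3L, from 18236680 to 18612349. The next were 296 kb on 3R, from 2287006 to 2583235, and 283 kb on 2L, from 14691122 to 14974156. A further 246 kb on 3R lay from 2644729 to 2890378. On each of the 5 large arms the longest stretch exceeded that of 1000 random placements of the same regions (one-sided adjusted permutation p = 0.001, the smallest the draws can give). For 3L, the random placements reached at most 114 kb. Random placement ignores the uneven density of regions along the arms, where 1 Mb bins ran from 4.70% to 36.1% covered. Longer stretches than in random placements follow from that density, so the p does not single out these stretches. This comparison was chosen after the data were examined, and unmappable sequence in the stretches was not assessed.

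The longest blocks were spread over the arms and were covered in both replicates. The whole-series block of 78.3 kb on 3L, from 17955115 to 18033384, was 96.0% covered in replicate 1 and 98.1% in replicate 2. The next longest was 45.04 kb on 2L, from 4069808 to 4114847, covered at 86.8% and 88.5%. A block of 43.2 kb on 2R, from 1061862 to 1105059, was covered at 77.6% and 67.5%. A block of 42.5 kb on 3R, from 9805783 to 9848266, was covered at 99.0% and 98.9%, with scores of 1.05 and 1.00. The other 6 of the 10 longest measured 39.5 to 42.4 kb and lay on X, 3R and 2L.

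Of the whole-series regions, 503 (4.07%) were at least 90% covered in both replicates. The 10 strongest of these by the lower replicate score lay on 2L, 2R, 3L, 3R, X and U. The first was 15.7 kb on 2L, from 167013 to 182754, with a score of 1.18 in each replicate. On X the strongest was 10.3 kb, from 15707318 to 15717647, with scores of 1.11 and 1.14. On 3L it was 9.43 kb, from 18795899 to 18805331, with scores of 1.25 and 1.04. On U a region of 3.21 kb, from 8581210 to 8584416, had scores of 1.17 and 2.70, the widest gap between replicates among the 10.

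The last comparison sets the whole-series list against the replicates. Nearly all of what the replicates marked was in it: 98.6% of the bases of replicate 1, 98.7% of those of replicate 2, and 17495919 of the 17496518 bases found in both. It added 10.9 Mb that no replicate covered. Of its regions, 4341 overlapped both replicates, 2318 replicate 1 alone and 1034 replicate 2 alone, and 4669 (37.8%, 95% Wilson interval 36.9 to 38.6) overlapped neither. The regions in neither had a median width of 1284 bp and a median score of 0.38, against 4773 bp and 0.51 for regions in both. As deposited, the shortest region was 1001 bp in this list and 1301 bp in each replicate. Without whole-series regions under 1301 bp, the share in neither was 23.1%.

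Relative to the replicate mean, the whole-series list extended H3K27me1 regions further in heterochromatin than on the arms. It covered 1.62 times the replicate mean on the autosomal arms, 1.72 times on X and 2.02 times on chromosome 4. On the placed heterochromatin it covered 19.03%, which was 3.18 times the replicate mean, and on U 7.44%, which was 4.91 times. These ratios start from low replicate means, 5.98% and 1.52%, against 19.4% on the autosomal arms and 21.1% on X. On the autosomal arms the whole-series list covered 31.5%, and on X 36.2%. As added share of the scaffold, the list therefore gained about as much on the placed heterochromatin as on the autosomal arms, and least on U. In neither replicate were 33.8% (32.8 to 34.8) of its autosomal arm regions, 61.9% (58.6 to 65.1) of its placed heterochromatin regions and 75.1% (71.0 to 78.8) of its U regions. Its highest score, 3.57, belonged to a region of 1019 bp on U, from 5899866 to 5900884, which was 99.2% covered in replicate 2 and not covered in replicate 1. The 4 next highest, at 3.31 to 3.45, overlapped neither replicate: 2 lay on 2RHet, 1 on U and 1 on 2L. The highest-scoring region of replicate 1 (3.13, on U from 2286168 to 2287533) overlapped neither of the other lists, and that of replicate 2 (3.91) overlapped the whole-series region with the highest score.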

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

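Of the 19 results recomputed under alternatives, none with a sign changed direction, and no call of the replicate overlap was lost. The centromere-proximal ratios and the ratio of XHet to the autosomal arms were not among them. On 2R the centromere-proximal ratio was 0.94 in replicate 1, 1.32 in replicate 2 and 1.35 in the whole-series list. The XHet ratio was 0.65, 0.63 and 1.21 in the same order. Under every alternative run for the replicate overlap the shift p stayed at 0.001, with a Jaccard index of 50.7% to 57.2%. The overlap rule moves only the share of shared regions, which was lowest, at 47.5% and 56.5%, when 50% of each region had to overlap. The width minimum of 1 kb removed 0 regions and so tests nothing. With each replicate alone, shares lie within the spread by construction; only the ratio of chromosome 4 to the autosomal arms, 0.60 against 1.00, rests on 1 library. With regions at or above the median score of each list alone the score correlation was 0.54, and 96.5% of replicate bases lay inside the whole-series regions kept. The covered shares were then 12.5% on the autosomal arms, 6.88% on chromosome 4, 3.98% on placed heterochromatin and 1.26% on U. The ratio to the autosomal arms became 1.40 for X and 0.10 for U. Both had higher scores than the autosomal arms, so a cut by score keeps more of their regions. Score differences from the autosomal arms shrank to 0.030 for X, -0.0037 for chromosome 4, 0.034 for placed heterochromatin and 0.16 for U; fewer low scores remain by construction. In the whole-series list the covered shares were 31.5% on the autosomal arms, 36.2% on X, 30.6% on chromosome 4, 19.03% on placed heterochromatin and 7.44% on U. Ratios to the autosomal arms were 1.15 for X, 0.60 for placed heterochromatin and 0.24 for U, and score differences were 0.068 for X, -0.043 for chromosome 4, 0.11 for placed heterochromatin and 0.29 for U. Leaving out whole-series regions under 1301 bp, chosen after seeing the data, lowered the share in neither replicate from 37.8% to 23.1%; of the 2672 regions left out, 2431 were in neither. The planned gene and annotation alternatives were not run. Read depth is unknown, so no limit from depth can be given. No paired analysis was possible because the input samples have no file here and the only group with values has 1 list per replicate number.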

Other observations

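The tests on wider regions of X, on weaker regions, on few reads per region and on heterochromatin at large, and the split of arms near the centromere, were chosen after the result they measure was seen. H3K27me1 coverage at the centromere-proximal ends of the arm scaffolds differed between arms. The proximal stretch is the 2 Mb of each large arm scaffold at its centromere side. Placed heterochromatin is on separate scaffolds, and the distance of each arm end from the centromere was not assessed. Differences between arms therefore cannot be tied to nearness to the centromere. On 3R the proximal stretch was covered at 30.3% in replicate 1 and 26.1% in replicate 2, against 20.4% and 16.2% in the rest of the arm. On 3L the proximal values were 9.68% and 9.31% against 22.4% and 18.1%, a ratio of 0.43 and 0.51 that was weaker, at 0.82, in the whole-series list, and on X 11.6% and 9.63% against 24.9% and 19.4%. On 2L the proximal stretch was covered 1.03 times the rest of the arm in replicate 1 and 1.34 times in replicate 2, and on 2R 0.94 and 1.32 times.

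The higher scores on X were not limited to part of the chromosome. Regions on X were not wider, with medians of 2197 and 2131.5 bp against 2285 and 2238 bp on the autosomal arms, which argues against width as the source (within quartiles of width the smallest difference was 0.075), and the smaller difference at the 25th percentile was 0.073, which argues against a few strong regions. All 22 of the 1 Mb bins of X with at least 20 regions had a median above the autosomal median in both replicates (100%), against 47 of 95 autosomal bins in replicate 1 and 41 of 94 in replicate 2. This is consistent with one offset for the whole X, which may be a property of the chromatin of X or of how ChIP and input were scaled on a chromosome present in different copy number in males and females. These lists hold no input values, so both stay open, and other explanations are not excluded. Scores exist only for regions that passed a call whose threshold is not given, so they do not measure the signal over all of X. Whether that call selected regions differently on X and on the autosomes cannot be told here. No biological explanation was tested because the design names no groups of larvae.

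Chromosome 4 was covered 1.34 times as much in replicate 2 as in replicate 1, while the autosomal arms were covered 0.81 times as much. Of 11230 windows of the length of chromosome 4 on the large arms, 0 (0%) had a ratio as high and the highest was 1.15. Chromosome 4 thus lay outside the range of the large arms. Neighbouring windows share most of their bases, the pattern had already been seen, and heterochromatin scaffolds are not among the windows. The windows therefore cannot decide whether regional variation between replicates accounts for the higher ratio on chromosome 4. More bases were called in replicate 1, which works against this pattern, and a planned test that matched replicate 1 to the covered bases of replicate 2 by score (2.56) is void, since leaving regions out can only raise the ratio. The ratio was 1.11 on the placed heterochromatin, with 1.19 on 2RHet, 1.23 on 3LHet and 0.99 on 3RHet, and 0.97 on U, all above the autosomal 0.81, but 0.78 on XHet and 0.77 on 2LHet over 4 to 11 regions per replicate. It was also higher in the centromere-proximal 2 Mb than in the rest of the arm on 5 of 5 large arms (exact sign test, two-sided p = 0.0625, the smallest 5 arms can give). The proximal ratios were 1.07 on 2L, 1.06 on 2R, 0.96 on 3L, 0.86 on 3R and 0.83 on X. In the rest of these arms they were 0.82, 0.75, 0.81, 0.79 and 0.78, so the gap was small on 3R and X. A candidate explanation, as a hypothesis, is that heterochromatin at large was better recovered or more marked in replicate 2. However, no proximal stretch and no heterochromatin scaffold named here reached 1.34.

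As a ratio, the whole-series list exceeded the replicate mean by more on the placed heterochromatin than on the autosomal arms, with a ratio 1.96 times as high. The added share of the scaffold was similar on both, from 5.98% to 19.03% and from 19.4% to 31.5%, so what follows concerns the ratio alone. Leaving out whole-series regions shorter than 1301 bp lowered this excess to 1.69, which argues against the shorter minimum width as the whole cause. Heterochromatic regions found in that list alone scored 0.020 above those found in both replicates (95% bootstrap interval -0.023 to 0.052), whereas on the autosomal arms the difference was -0.15 relative to those found in both, so whether weaker regions are the source in heterochromatin stays open. Scores that recur exactly in the list, as ratios of small read numbers would, made up 52.0% (47.7 to 56.2) of the heterochromatic regions found in that list alone, 49.3% (47.5 to 51.1) of such regions on the autosomal arms and 9.32% of autosomal regions found in both. Among regions found in that list alone this share was 59.8% (54.6 to 64.8) on U, 56.8% (53.4 to 60.1) on X and 33.3% on chromosome 4, so whether few reads per region account for the excess in heterochromatin stays open.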
